A study of Homo sapiens with 2 samples.

How the data were processed

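RNA was sequenced from HCC1954 cells in 2 libraries, 1 labelled ASO-NC and 1 labelled ASO-1235 by genotype. Per the labels' protocols, polyadenylated RNA was captured on beads, fragmented and reverse transcribed with random hexamers before adapter ligation and PCR. The sample title of the ASO-1235 library uses the prefix Si in place of ASO, and the genotype label was followed.

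The deposited table holds raw counts per gene, which the authors did not normalize as far as the values show: they are whole numbers with a different total in each library. STAR 2.7.11a, featureCounts 2.0.6 and genome build hg38 are named, per the submitters' processing notes. The annotation release, the strand setting and the filters are not given in the sources used here. Reads of overlapping or antisense genes therefore cannot be told apart, and reads of near-identical copies are uncertain. The table held 62699 versioned Ensembl gene IDs with counts, all of which matched a name, which for some genes was only the ID without its version. For 1 further ID the table had no counts, followed by 2 lines of exon coordinates in their place, and it was left out. Coordinates, transcript length and GC content came from GENCODE 29 on GRCh38, in which 58206 of the IDs were found without their version. The longest transcript stood for each gene.

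Among genes with 1 to 1000 counts, 67.5% of counts in the ASO-NC library and 64.0% in the ASO-1235 library were even numbers, where single reads would give about 50%. Each mate of a read pair seems to have been counted on its own, so counting intervals taken from the deposited counts are too narrow. Intervals on halved counts were computed as well, a choice made after the data were seen. Intervals and floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

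Libraries were scaled with TMM (edgeR 4.0.16 in R 4.3.3), with factors of 0.971 for ASO-NC and 1.03 for ASO-1235. edgeR served for scaling alone, since 1 library per group leaves no spread to test against. For each gene the ratio ASO-1235 over ASO-NC was taken with an exact (Clopper-Pearson) 95% interval given the sum of both counts. A gene was called higher or lower when it reached 1 CPM in at least 1 library, differed by at least 2-fold and had an interval that excluded 1. For a gene with 0 counts in a library, a floor of 3 counts stood in for the 0. A fold against this floor leaves out the counting error of the other library. At the depth of these libraries the floor amounts to 0.0624 CPM in ASO-NC and 0.0791 CPM in ASO-1235.

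Before the data were examined, 40 gene lists were fixed for this cell line and treatment, including markers of other cell types. For each of the 37 lists with at least 5 members at 1 CPM, the median log2 ratio was computed with a prior count of 0.5 scaled to library size. Its percentile came from 10000 random lists of the same size matched on mean expression in 20 bins. A list stood apart outside the central 95% of these, as a description of these libraries. Members were counted as higher or lower at 1.5-fold with an interval that excluded 1. Intervals of medians are sign-based, and exact only if the members of a list vary independently. For genes regulated together they are too narrow.

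The genes named were chosen by a rule fixed at the same time: LINC01235, NFIB and ERBB2, the 12 highest and 12 lowest genes by the bound of the interval nearest to 1, and up to 3 members each way of each list that stood apart or up to 2 members each way past 1.5-fold of the others. Clone names were left out of this rule. The text names part of the genes that the rule selects, and the others are not reported here. Genes named beyond it were chosen after their values were seen: the other neighbours of LINC01235, the abundant genes at 2-fold, a few further list members such as ISG15, IFNL1, CCL2 and SAMD9L, and the groups of the closing section.

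A trend of the log2 ratio on GC content and log2 transcript length was fitted by robust regression on splines with 5 degrees of freedom each (statsmodels 0.14.6), after the data were seen, and removed as an alternative. GC content and length were known for 97.7% of the genes kept. Other alternatives were scaling by DESeq2 1.42.0 size factors, upper quartile or total count, other minimum counts, other sizes of change, other intervals and a prior count of 5. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

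The calculation was tested on simulated data for ASO-1235 against ASO-NC, drawn from the mean and library size of 14352 genes with 200 changed. When both mates of each pair were counted, the interval held the true ratio for 84.4% of 14152 unchanged genes, and that on halved counts for 95.9%. In that simulation 46 unchanged genes were called at 2-fold, and all 66 genes changed by 3-fold, 34 of 67 changed by 2-fold and 0 of 67 changed by 1.5-fold were called. Of 20 simulated lists of 25 genes shifted by −0.25 on the log2 scale, 20 stood apart before and after trend removal, against 0 and 1 of 20 unchanged lists. The simulation held no differences between cultures, and its lists were genes drawn at random. Its rates of false calls therefore do not measure those in these libraries, whose counts spread more widely than counting error.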

Results

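Gene expression was measured by RNA sequencing of polyadenylated RNA in HCC1954 cells, an established human breast cancer cell line in which the ERBB2 gene, which encodes the HER2 receptor, is amplified. By their genotype labels, 1 library came from cells given ASO-NC and 1 from cells given ASO-1235. ASO is the usual abbreviation of antisense oligonucleotide, and the series title names the long non-coding RNA LINC01235 as its subject. The series asks how LINC01235 affects transcription in these cells. The ASO-NC library held 48092494 counts over 26353 genes, and the ASO-1235 library held 37916307 counts over 27088 genes. Each group has 1 library, so no difference has a replicate check, no p-value is given, and every count of genes compares these libraries, not the conditions. Ratios are ASO-1235 over ASO-NC on TMM-scaled libraries. Their 95% intervals are exact for the counts as deposited and cover counting error only. They are too narrow if each mate of a pair was counted on its own. In the simulation of that case they held the true ratio for 84.4% of unchanged genes.

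LINC01235, the named target, had 1337 counts (28.6 CPM) in the ASO-NC library and 0 counts in the ASO-1235 library. With a floor of 3 counts in the ASO-1235 library, it was at least 373-fold lower there. The table alone does not show whether this 0 was a measured absence or arose when the table was made. The gene (ENSG00000270547.6) lies on chromosome 9 from 13406380 to 13433053 on the minus strand (GRCh38, GENCODE 29). It is annotated as an intergenic long non-coding RNA with 2 transcripts of 3 exons each, the longest of 2328 nucleotides. No annotated gene overlaps it, and the nearest, a non-coding gene 13.4 kb away, had 0 counts in both libraries. Within 1.5 Mb, 4 protein-coding neighbours reached 1 CPM, with counts in both libraries. NFIB, a transcription factor gene 649 kb away, had 1780 and 1489 counts, a log2 ratio of 0.00 (−0.10 to 0.10). MPDZ, a scaffold protein gene 127 kb away, had 575 and 500 counts, and LURAP1L had 368 and 332. ERBB2 stood at 4860 and 4628 CPM, a ratio of 0.952 (0.946 to 0.958), which lay above 1 when libraries were scaled by their total count.

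Outside LINC01235, the libraries were alike for most genes. Of 14352 genes at 1 CPM or more in at least 1 library, 90.4% lay within 1.5-fold. At 2-fold, with an interval that excluded 1, 363 genes were higher and 74 lower in the ASO-1235 library. At 1.5-fold, 919 were higher and 423 lower. Most calls were of weakly expressed genes: 311 of the higher and 69 of the lower ones lay among the 2871 genes of lowest expression, at a mean of at most 3.11 CPM, and with a minimum of 5 CPM the counts were 49 higher and 1 lower. Among the 8611 genes at a mean of 12.0 CPM or more, 16 were at least 2-fold higher and LINC01235 alone was at least 2-fold lower.

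These 16 abundant genes were listed together after their values were seen. The highest ratio was that of KLF10, a Krüppel-like factor inducible by TGF-beta, which had 4334 counts in the ASO-NC library and 12227 in the ASO-1235 library, a ratio of 3.37 (3.26 to 3.49). CREB5, a factor that binds cyclic AMP response elements, had a ratio of 2.99 (2.75 to 3.25). The clock gene PER1 was at 2.73 (2.45 to 3.04), CREBRF at 2.68 (2.44 to 2.94) and ID4, an inhibitor of DNA binding, at 2.62 (2.31 to 2.98). The immediate early gene EGR1 was at 2.41 (2.24 to 2.58), the stress-inducible factor ATF3 at 2.34 (2.08 to 2.63), the aryl hydrocarbon receptor gene AHR at 2.34 (2.16 to 2.54) and the NF-kB subunit gene RELB at 2.02 (1.79 to 2.28). The others were PGM2L1, ZBTB10, ANXA1, PTPN21, STON1, ARRDC3 and ZC3H6, with ratios from 2.04 to 2.62. After removal of the GC and length trend, 4 of the 16 lay under 2-fold: AHR at a log2 ratio of 0.99, STON1 at 0.87, ARRDC3 at 0.82 and ZC3H6 at 0.76.

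**Figure D1:**
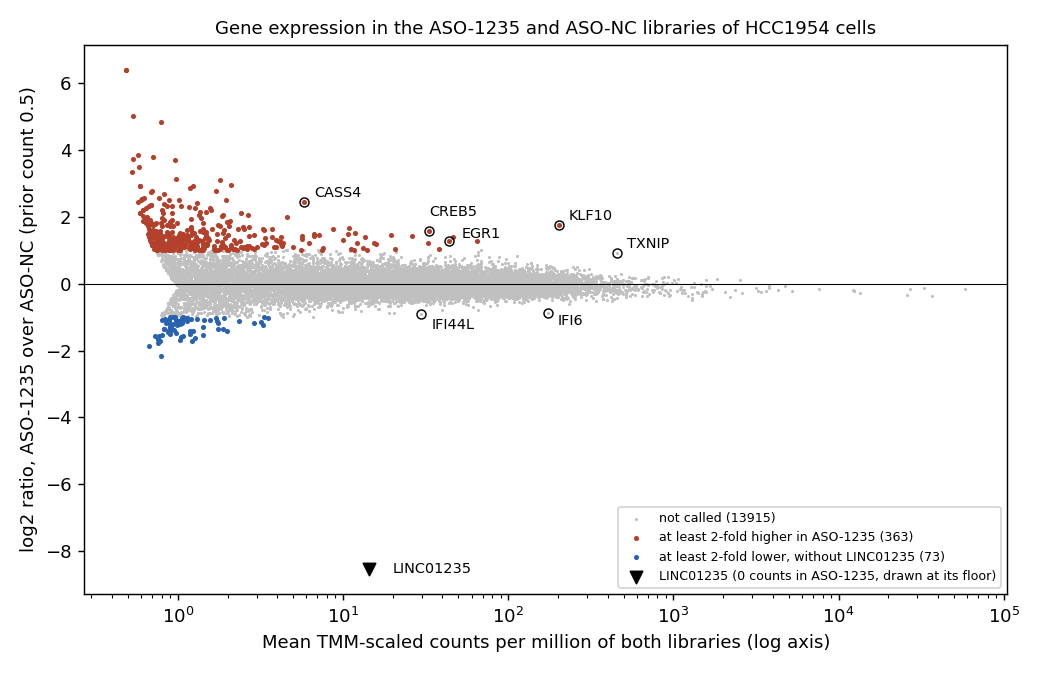
Log2 ratio of each of 14352 genes (ASO-1235 over ASO-NC, vertical axis) against its mean TMM-scaled CPM in both libraries (logarithmic horizontal axis); red and blue points are genes at least 2-fold higher and lower, and the black triangle is LINC01235 at its floor. LINC01235 lies far below all other genes, most other called genes lie at low expression, and KLF10 stands out among abundant genes.

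By the bound of the interval nearest to 1, the 12 highest genes were mostly near the detection limit in the ASO-NC library. ACTA2, which encodes smooth muscle actin, and LINC01476 each had 0 counts there and 38 in the ASO-1235 library, 15.1-fold higher against a floor of 3 counts. The lower bound of the interval was 11.7-fold for each, and 5.58-fold on halved counts. SLC6A19, a neutral amino acid transporter gene, had 2 and 60 counts, and CLTRN, which encodes its partner protein collectrin, had 9 and 69. SDS, which encodes serine dehydratase, had 13 and 86 counts, and the adhesion receptor gene ADGRF5 had 4 and 52. CASS4, a gene of the Cas scaffold family, was the most abundant of them, with 84 and 384 counts and a ratio of 5.47 (4.31 to 7.01). The others were LST1, LINC00612, CRTAC1, TRIM67 and LINC02067, with ratios from 6.94 to 16.7. After LINC01235, the lowest were LINC01786 (61 and 11 counts), HSD17B1, which encodes an enzyme of estradiol synthesis (90 and 24), SGSM3 (74 and 19), the G protein gene GNA14 (99 and 28) and LINC02826 (49 and 11). ATP5ME, an ATP synthase subunit gene, had 136 and 42 counts, MIR200CHG, the host gene of miR-200c and miR-141, had 75 and 21, and MZB1 had 215 and 76. ASPG, STEAP1 and C1GALT1C1 completed the 12, with ratios from 0.283 to 0.328.

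Proliferation genes were lower in the ASO-1235 library by small amounts. All 34 measured genes of G1/S and S phase had ratios below 1 (28 of them with scaling by total count), with a median log2 ratio of −0.26 (sign-based 95% interval −0.35 to −0.17), below all 10000 random lists of matched size and expression. TK1, the thymidine kinase of S phase, had 3992 and 2212 counts, a ratio of 0.663 (0.629 to 0.698), and was the single member past 1.5-fold. TYMS was at 0.719 (0.667 to 0.775) and the DNA polymerase alpha subunit gene POLA2 at 0.686 (0.611 to 0.768). Of 26 genes of DNA replication licensing and origin firing, 22 had ratios below 1, with a median of −0.25 and a percentile of 0. The helicase genes MCM5 and MCM7 were at 0.692 (0.655 to 0.731) and 0.707 (0.689 to 0.725), and CDC45 was at 0.706 (0.653 to 0.763). ORC4, which encodes a subunit of the origin recognition complex, had a ratio of 1.35 (1.26 to 1.44). Among 38 genes of G2/M and mitosis, 35 had ratios below 1, with a median of −0.18 and a percentile of 0.03. The mitotic kinase gene AURKB was at 0.687 (0.631 to 0.748) and FOXM1, which encodes a transcription factor of mitotic genes, at 0.730 (0.702 to 0.759), whereas HMMR was at 1.37 (1.27 to 1.48). DNA damage repair genes had a median of −0.13 and a percentile of 1.83 (21 of 30 ratios below 1, and 16 with scaling by total count), with RAD54L at 0.644 (0.545 to 0.760), FANCA at 0.695 (0.644 to 0.750) and ATM at 1.27 (1.19 to 1.35). No member of the licensing or mitosis lists passed 1.5-fold.

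Interferon-stimulated genes were lower in the ASO-1235 library, although not all of them. Of 36 genes of the type I interferon response at 1 CPM, 8 were at least 1.5-fold lower and 1, SAMD9L, at least 1.5-fold higher, and the median log2 ratio of −0.30 (−0.44 to −0.09) lay below all 10000 random lists. IFI6, which encodes an interferon-induced mitochondrial protein, had 10456 and 4773 counts, a ratio of 0.546 (0.527 to 0.565). IFI44L was at 0.531 (0.488 to 0.577), the ubiquitin-like modifier gene ISG15 at 0.538 (0.486 to 0.596) and XAF1 at 0.370 (0.229 to 0.581). IFNL1, which encodes an interferon of type III, was at 0.635 (0.557 to 0.723). OASL, HERC5 and SAMD9 had ratios of 1.20 (1.12 to 1.28), 1.23 (1.09 to 1.38) and 1.23 (1.09 to 1.39). Antigen presentation genes had the lowest median of the 37 lists with a percentile, −0.34 (−0.57 to −0.11), also below all random lists, and 13 of 16 had ratios below 1. NLRC5, the transactivator of MHC class I genes, was at 0.583 (0.499 to 0.679), the immunoproteasome subunit gene PSMB10 at 0.569 (0.472 to 0.683) and HLA-C at 0.697 (0.681 to 0.714). In the other direction, HLA-DMA of the class II pathway had 30 and 65 counts, a ratio of 2.59 (1.66 to 4.14). HLA genes resemble each other in sequence, so the counts of single HLA genes are uncertain.

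NF-kB and inflammatory cytokine genes were higher in the ASO-1235 library. Of 22 members at 1 CPM, 9 were at least 1.5-fold higher and 0 lower, and the median of 0.39 (−0.01 to 0.91) lay above all 10000 random lists. CXCL8, the gene of the neutrophil chemokine interleukin 8, had 270 and 554 counts, a ratio of 2.45 (2.12 to 2.85). IL23A was at 3.38 (1.91 to 6.26) from 17 and 48 counts, CCL2 at 1.87 (1.62 to 2.17) and BIRC3, which encodes an inhibitor of apoptosis, at 1.78 (1.61 to 1.97). CCL5 and BCL3 had ratios of 0.899 (0.864 to 0.936) and 0.865 (0.808 to 0.927).

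**Figure D2:**
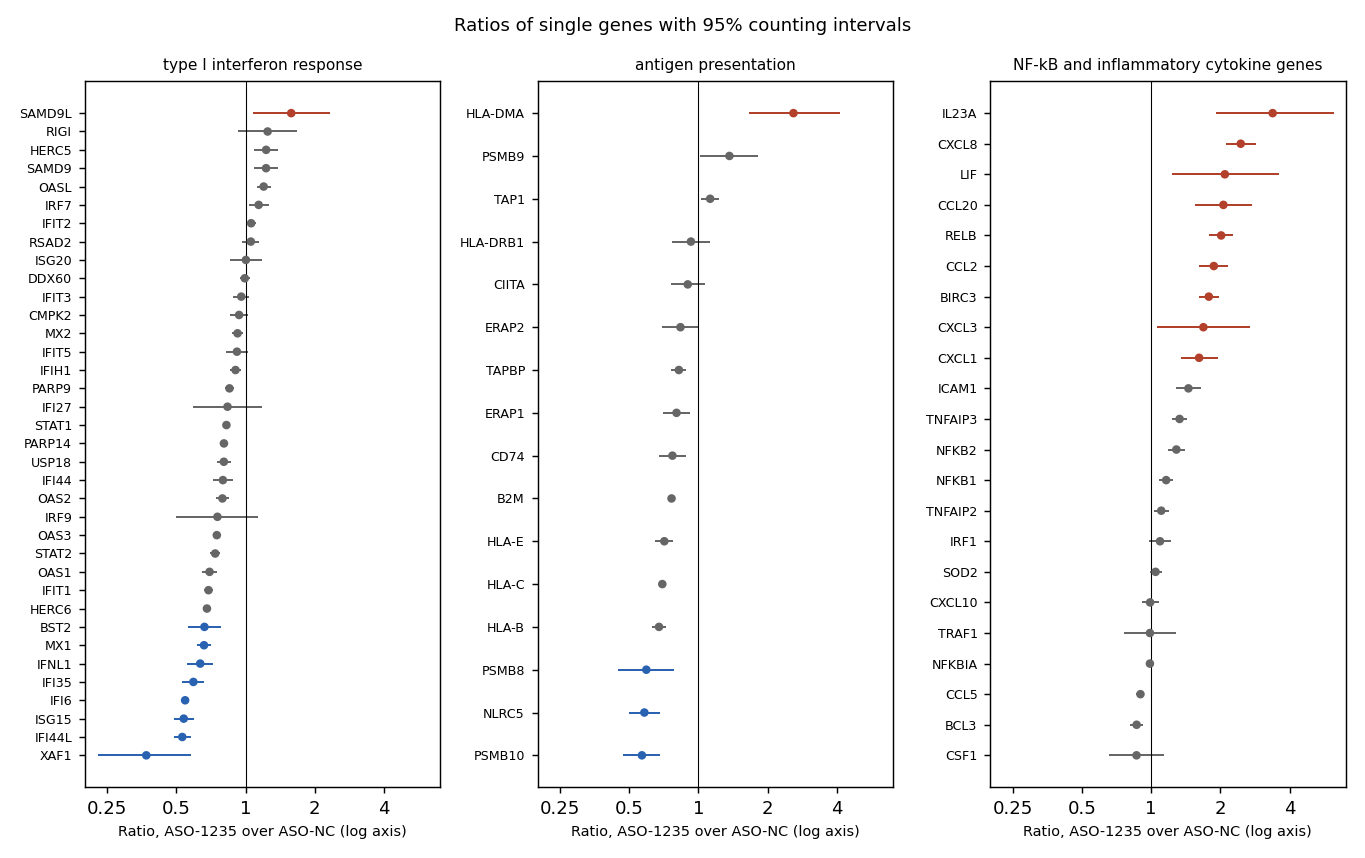
Ratio of each member of 3 gene lists (ASO-1235 over ASO-NC, logarithmic horizontal axis) with its 95% counting interval as a line; red and blue mark members at least 1.5-fold higher or lower with an interval that excludes 1, and grey the rest. Interferon response genes spread from 0.370 for XAF1 to 1.58 for SAMD9L, while the NF-kB list reaches 3.38 for IL23A.

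Transcripts of the translation machinery and of mitochondrial respiration were lower as groups. Of 73 cytosolic ribosomal protein genes, 72 had ratios below 1 (62 with scaling by total count), and the median of −0.27 (−0.30 to −0.24) lay below all random lists. RPS21 was at 0.619 (0.585 to 0.655) and the single member past 1.5-fold, RPL38 was at 0.690 (0.665 to 0.717), and RPL22 was the exception at 1.06 (1.02 to 1.11), with an interval that included 1 on halved counts. Ribosomal protein genes have many pseudogenes, so the counts of single members are uncertain. Nuclear genes of oxidative phosphorylation had a median of −0.19 (−0.23 to −0.13) with 37 of 44 ratios below 1. NDUFS8 and COX6B1 were at 0.733 (0.711 to 0.755) and 0.747 (0.715 to 0.780). At least 1.5-fold higher were 2 members, NDUFV2 at 1.74 (1.37 to 2.20) from 124 and 180 counts and NDUFB5 at 1.51 (1.36 to 1.67) from 669 and 845. All 13 mitochondrially encoded mRNAs had ratios below 1, with a median of −0.22 and a percentile of 1.0, among them MT-CO2 at 0.770 (0.768 to 0.772). Mitochondrially encoded genes took 26.5% of the counts in the ASO-NC library and 24.1% in the ASO-1235 library.

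Among metabolic and stress lists, cholesterol synthesis genes had a median of −0.22 and a percentile of 0.08. The sterol isomerase gene EBP was at 0.569 (0.501 to 0.645) and MVD at 0.693 (0.638 to 0.752), against SC5D at 1.34 (1.26 to 1.44). NRF2 target genes had a median of −0.21 and a percentile of 0.25. The ferritin genes FTH1 and FTL were at 0.746 (0.737 to 0.755) and 0.809 (0.794 to 0.825), and the glutamate-cysteine ligase gene GCLM was at 1.24 (1.08 to 1.41). Genes of the amino acid response and ER stress had a median of −0.14 at percentile 1.74, but its members went both ways: SHMT2 and PHGDH of serine and glycine synthesis were at 0.774 (0.738 to 0.812) and 0.790 (0.751 to 0.830), while DDIT3, the gene of the stress factor CHOP, was at 1.51 (1.37 to 1.67). With a minimum of 5 CPM that list lay at percentile 71.4.

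A further 5 groups lay above the central 95% of random lists. Immediate early genes had a median of 0.15 (0.01 to 0.83), with 6 of 22 members at least 1.5-fold higher, including EGR2 at 5.38 (2.67 to 12.0) from 10 and 45 counts, and EGR3 lower at 0.642 (0.434 to 0.937), a call lost on halved counts (0.36 to 1.1). NR4A1 of the same list was at 0.703 (0.627 to 0.788). Of 27 p53 targets, 22 had ratios above 1, with a median of 0.15 and a percentile of 98.9. CDKN1A, which encodes the cell cycle inhibitor p21, was at 1.54 (1.43 to 1.67) and the single member past 1.5-fold, GDF15 was at 1.48 (1.32 to 1.66), and PHLDA3 was at 0.840 (0.772 to 0.913). Cell death genes had a median of 0.14 (−0.004 to 0.26) and a percentile of 97.7, with 16 ratios above and 6 below 1. The 2 members past 1.5-fold were the inhibitor gene BIRC3 at 1.78 and HRK at 1.74 (1.19 to 2.57) from 48 and 70 counts. The inhibitor gene XIAP was at 1.30 (1.22 to 1.38) and BCL2 at 0.827 (0.753 to 0.909). TGF-beta and BMP targets had a median of 0.18 (−0.07 to 0.44) and a percentile of 99.3, with 5 of 22 members at least 1.5-fold higher, among them TGFB2 at 5.41 (3.26 to 9.42) from 19 and 86 counts, whereas ID1 was at 0.849 (0.804 to 0.897). YAP and TEAD targets had a median of 0.25 (0.04 to 0.65) and a percentile of 99.6, also with TGFB2, and with ANKRD1 at 3.99 (2.05 to 8.35), PTPN14 at 1.75 (1.63 to 1.87) and IGFBP3 at 0.763 (0.700 to 0.832). With a minimum of 5 CPM the immediate early list lay at percentile 89.7 and the YAP list at 96.6.

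The remaining 19 lists with a percentile lay within the range of random lists. The Notch pathway had a median of −0.03 at percentile 41.4, with MFNG as the single member past 1.5-fold at 0.643 (0.416 to 0.977), a call lost on halved counts (0.341 to 1.17). The NFI factors and chromosome 9 neighbours of LINC01235 had a median of 0.06. The ERBB2 amplicon had a median of −0.08. ERBB receptors and ligands had a median of 0.16 at percentile 96.5, with the ligand genes EREG at 2.87 (1.91 to 4.39) and AREG at 1.55 (1.32 to 1.82). Mesenchymal transition genes had a median of 0.32 at percentile 95.4, with CDH2, the gene of N-cadherin, at 3.65 (2.53 to 5.35) from 40 and 122 counts, and SNAI1 at 0.598 (0.358 to 0.975), which included 1 on halved counts (0.282 to 1.21). With a minimum of 5 CPM the ERBB list was at −0.03 (percentile 54.1) and the mesenchymal list at 0.0045 (55.8). Breast stem and progenitor genes lay at percentile 95.9, with LGR5 at 7.03 (3.29 to 17.2) from 8 and 47 counts. MAPK feedback and target genes had a median of 0.02 at percentile 58.8, with SPRY2 and SPRED1 at 1.79 (1.37 to 2.35) and 1.71 (1.46 to 2.02) and DUSP6 and DUSP4 at 0.872 (0.805 to 0.945) and 0.905 (0.886 to 0.923). Other cell types left little trace: of the marker genes of immune cells, 1 reached 1 CPM (LYZ, 98 and 44 counts), and of those of fibroblasts and of endothelial cells and adipocytes, 3 each, including FAP (28 and 53 counts) and FBLN1 (1236 and 646).

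**Figure D3:**
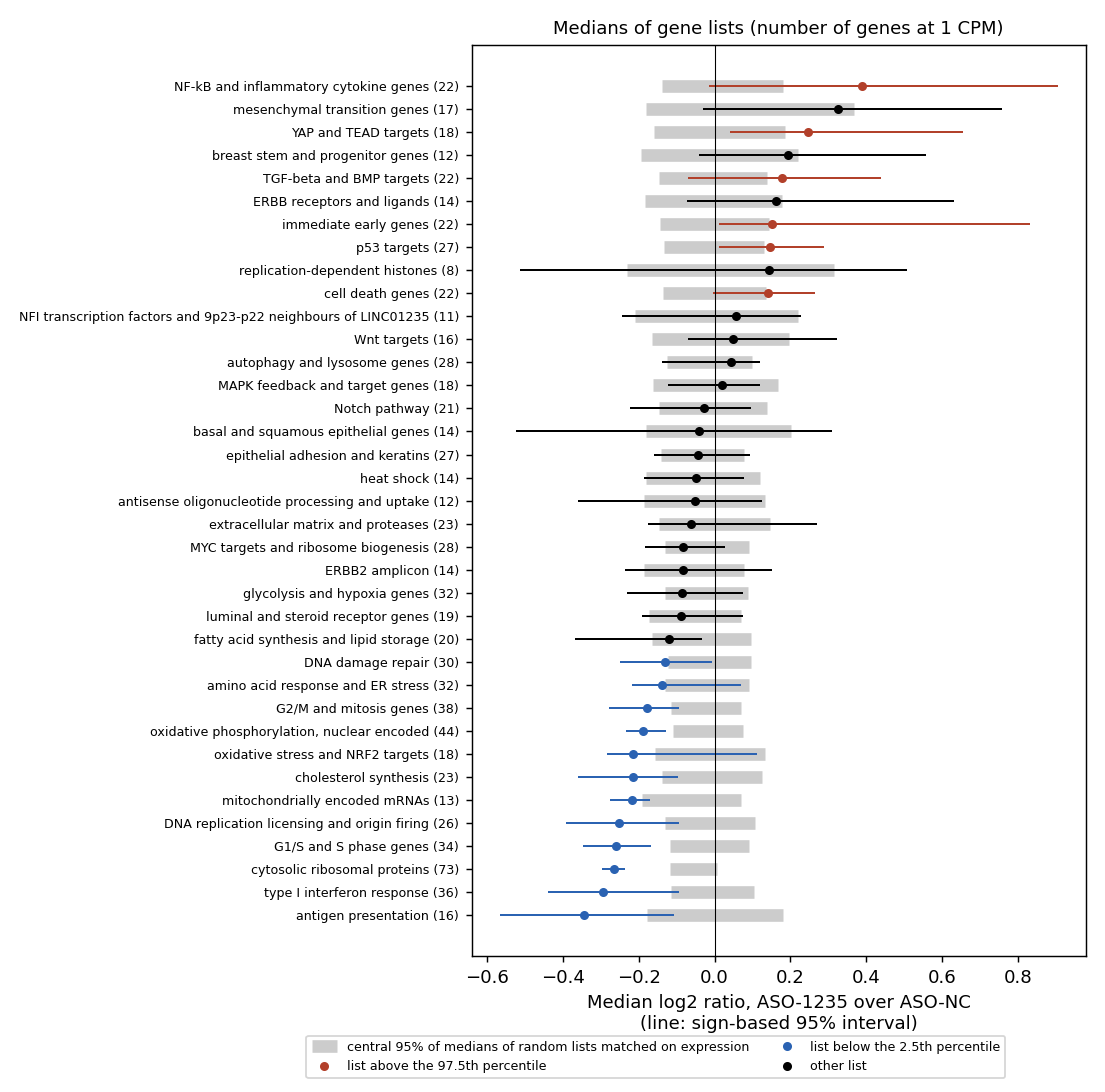
Median log2 ratio (ASO-1235 over ASO-NC, horizontal axis) of 37 gene lists with its sign-based 95% interval as a line, over grey bars for the central 95% of medians of random lists matched on expression; the number of genes is in parentheses. Blue lists, such as cytosolic ribosomal proteins at −0.27, lie below the grey bars and red ones, such as the NF-kB list at 0.39, above them.

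Of the 37 lists, 12 lay below and 6 above the central 95% of random lists, where chance would put 1.85 outside if the genes of a list varied independently, which genes regulated together do not. The ratio also moved with the sequence of the transcripts: the median log2 ratio was 0.21 in the 2804 genes with the lowest GC content and −0.19 in the 2804 with the highest, and −0.10 in the 2804 with the shortest and 0.11 in the 2803 with the longest transcripts. Given the sum of both counts, counts in the ASO-1235 library spread 2.39 times as widely as counting error among the 2871 genes of lowest expression. Among the 2870 of highest expression the factor was 8.29. The log2 ratios themselves spread less in that group, with an SD of 0.222 against 0.726 among the genes of lowest expression. Counting error was computed with each count as an independent read, so separate counting of mates would add to both factors. These factors also hold the trend and any differences between the cultures or preparations.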

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

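The alternatives with halved counts, with the GC and length trend removed, and without mitochondrially encoded genes in the totals were chosen after the data were seen. The counts of called genes depended on the minimum expression and the size asked for. Without a minimum, 1769 genes were higher and 723 lower, and with 5 CPM 49 and 1. At 1.5-fold the counts were 919 and 423, and at 3-fold 114 and 14. With an interval that excluded 1.5-fold, 257 genes were higher and 42 lower. Halved counts gave 344 higher and 71 lower genes, all among the main calls, and removal of the trend 328 and 65, of which 294 and 54 were among them. Scaling by total count moved all log2 ratios up by 0.085: 421 genes were then higher and 60 lower. LINC01235 was then at −8.46 on the log2 scale (351-fold lower against the floor), and ERBB2 at 0.01. That scaling set the medians of DNA damage repair to −0.045, G2/M genes to −0.093, oxidative phosphorylation to −0.10, mitochondrially encoded mRNAs to −0.13, ribosomal proteins to −0.18 and autophagy and lysosome genes to 0.13. Removal of the trend set G2/M genes to −0.29, DNA damage repair to −0.26, ribosomal proteins to −0.21 and immediate early genes to 0.29 (percentile 100). The cause of these shifts beyond the settings themselves was not tested. Of the 18 lists that stood apart, 15 did so in all 7 alternatives, and no median of the 18 changed sign. The exceptions were the amino acid list (percentile 71.4 at 5 CPM, 5.82 after trend removal), the YAP list (96.6 at 5 CPM) and the immediate early list (89.7 at 5 CPM, 97.0 with genes of at least 1 count). After trend removal the mesenchymal and epithelial lists also stood apart, at percentiles 98.3 and 99.1, as did glycolysis and hypoxia genes at 5 CPM (1.46) and breast stem and progenitor genes with genes of at least 1 count (98.2). No paired analysis was possible because each group has 1 library, which also leaves no replicate to leave out. Of the 437 calls at 2-fold, 380 lay among the 2871 genes of lowest expression, and no alternative varied depth.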

Other observations

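Several families that had no fixed list of their own stood out once the abundant genes had been seen. They were then measured over lists of their members drawn up at that point. These lists overlap the fixed ones: KLF10 and KLF2, for instance, were also in the immediate early list. Of 18 detected core clock genes, 16 had ratios above 1 (17 with scaling by total count). In the ASO-1235 library 5 of them were at least 1.5-fold higher, and the median log2 ratio was 0.25. PER1 was at 2.73, HLF at 1.80 (1.58 to 2.05), the REV-ERB gene NR1D2 at 1.59 (1.52 to 1.67), BHLHE41 at 1.56 (1.37 to 1.79) and CRY1 at 1.53 (1.41 to 1.67), while DBP was at 0.913 (0.788 to 1.06). After removal of the GC and length trend, CRY1 and NR1D2 lay under 1.5-fold, at log2 ratios of 0.40 and 0.46, and CLOCK was at −0.083. Among 5 detected alpha-arrestins, 3 were at least 1.5-fold higher and the other 2 had ratios below 1. TXNIP, a glucose-responsive inhibitor of thioredoxin, had 14698 and 23111 counts, a ratio of 1.88 (1.84 to 1.92), ARRDC4 was at 2.0 (1.89 to 2.11) and ARRDC3 at 2.04 (1.90 to 2.19), but ARRDC1 was at 0.756 (0.729 to 0.784). Of 17 detected genes among KLF1 to KLF17 and SP1 to SP4, 4 were at least 1.5-fold higher and 0 lower. Their ratios split into 11 above and 6 below 1 (13 and 4 with scaling by total count). Besides KLF10, KLF11 was at 1.81 (1.68 to 1.96), KLF6 at 1.78 (1.71 to 1.86) and KLF7 at 1.69 (1.57 to 1.82), with KLF2 at 0.902 (0.820 to 0.992, and 0.787 to 1.03 on halved counts). Of 9 detected genes of the aryl hydrocarbon receptor and its targets, 2 were at least 1.5-fold higher and 0 lower. Of the ratios, 6 lay above and 3 below 1 (8 and 1 with scaling by total count). CYP1A1, the classical target of the aryl hydrocarbon receptor, was at 1.52 (1.46 to 1.58), and TIPARP, another of its targets, at 1.44 (1.34 to 1.55), while NQO1 was at 0.883 (0.847 to 0.921).

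A mixed list held secreted apocrine genes and cystatin genes, with LGALS3BP and CLU. Of its 14 detected genes, 5 were at least 1.5-fold lower in the ASO-1235 library and 0 higher. The list was made after some of its members had been seen to be low. Ratios were below 1 in 13 of the 14, with scaling by TMM and by total count alike, and the median log2 ratio was −0.50. MUCL1, the gene of small breast epithelial mucin, had 13167 and 7154 counts, a ratio of 0.650 (0.631 to 0.669). The cystatin genes CST4 and CST1 were at 0.575 (0.535 to 0.618) and 0.643 (0.613 to 0.675), the prolactin-induced protein gene PIP at 0.661 (0.583 to 0.748), the mammaglobin gene SCGB2A2 at 0.691 (0.659 to 0.725) and LGALS3BP at 0.581 (0.549 to 0.614). The intervals of LTF (0.761 to 1.02) and AZGP1 (0.724 to 1.16) included 1, and SCGB2A1, at 60 and 54 counts, had a ratio of 1.08 (0.731 to 1.58). After trend removal CST1 and MUCL1 lay within 1.5-fold, at log2 ratios of −0.44 and −0.56, whereas SCGB2A2 moved beyond it, to −0.67.

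Both tests of the loss of LINC01235 below were chosen after its counts had been seen, while the tests of the gene lists were set before their outcome was known. The absence of LINC01235 from the ASO-1235 library goes against chance: of 8955 genes with at least 500 counts in a library, 0 others had no count in the other library, and the largest count of another gene lost in this way was 42. Loss of the whole region is argued against by the 4 protein-coding neighbours within 1.5 Mb at 1 CPM, whose median log2 ratio was 0.083, with values from 0.00 to 0.23. A candidate explanation is that the transcript was removed by the oligonucleotide, but the counts cannot separate degradation of the RNA from a change of the gene itself or a row altered when the table was made, and none of these was tested.

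The interferon and NF-kB lists moved apart, and the trend of the ratio with GC content and transcript length may move any list. After its removal the interferon median was −0.34 (−0.48 to −0.12) and the NF-kB median 0.55 (0.10 to 0.84), both outside all 10000 random lists. The trend as fitted, on the longest transcript of each gene, therefore does not account for them. A fit on the transcripts that the cells express was not made, so a remainder of the trend cannot be ruled out. The antigen presentation median stayed below all random lists at −0.34, but its interval reached 0 (−0.52 to 0.05) and leaves that list open. An effect of ASO-1235 and a difference between the cultures both stay open and untested, since 1 library per group cannot separate them. There is also no untreated library, so a ratio does not show which of the libraries changed. With no other group aimed at LINC01235, an effect of ASO-1235 could not be tied to that transcript.

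Ribosomal protein, oxidative phosphorylation and S phase lists were lower in the ASO-1235 library. Removal of the GC and length trend left medians of −0.21 (−0.26 to −0.17), −0.16 (−0.24 to −0.10) and −0.26 (−0.34 to −0.23). This argues against the trend, as fitted on the longest transcripts, as their whole source. A general shift towards short-lived transcripts would raise zinc finger mRNAs and divergent promoter transcripts. The 444 zinc finger genes had a median of 0.099 (0.065 to 0.12) at percentile 100 before trend removal, as that explanation would have it. After removal the median of 440 of them was 0.022 (−0.01 to 0.05) at percentile 96.3, under the bound set for it but by less than its interval. The divergent transcripts had one of 0.18 at percentile 99.8 after (164 genes) and lay at 97.2 before (165 genes), which leaves it open for that class. For these lists too, an effect of ASO-1235 cannot be told apart from a difference between the cultures, and neither was tested. The lack of an untreated library and of another group aimed at LINC01235 limits them in the same way.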
